A study of Mus musculus with 8 samples.

How the data were processed

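H3K9ac was profiled in ileal epithelial cells of mice given vehicle or butyrate, with 3 libraries per group and 1 input library per treatment. Per the labels' protocols, sonicated chromatin from nuclear lysates was precipitated with an antibody to H3K9ac (Millipore), libraries were made with the ThruPLEX kit, and 100 bp paired-end reads were sequenced on a NovaSeq. The submitters' processing notes name the build mm10 and the tools STAR, Picard, HOMER and, used by the authors, edgeR, with no version, role or order. How regions were called and merged, on which libraries, and how reads were counted are not given in the sources used here.

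A single deposited table was used. Per the file headers it gives 11251 merged regions with an annotation and nearest gene, RPKM values per library, the authors' mean RPKM and mean CPM per group, and the authors' log2 fold change, log2 CPM, p-value, FDR and status. The deposited RPKM values were tested on the file: they are per kilobase of region length (end minus start) and scaled to an effective library size. The deposited mean CPM of a group equals its mean RPKM times the length. The deposited FDR equals the Benjamini-Hochberg adjustment of the deposited p-values over all 11251 regions, and the status follows an FDR of 0.1. The deposited log2 fold changes are butyrate over vehicle. Column names gave the group of each library (S1 to S3 vehicle, S4 to S6 butyrate) and no sample, and no columns of inputs were used.

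RPKM times length was a whole multiple of 1 step per library for 100% of values (tolerance 0.01 reads). This gave the reads per region and effective library sizes of 25805595, 17846924 and 20673786 reads for S1 to S3 and 22190474, 17909553 and 22512631 for S4 to S6. Reads in regions were 1828591, 1261630 and 1449476 in vehicle and 1554268, 1255251 and 1596958 in butyrate, about 7% of the effective sizes in every library. The lower quartile of regions had under 35.3 mean reads, the median 97.7 and the upper quartile over 184, so that counting error alone is large in the weakest regions. The effective sizes were 0.998 to 1.001 times those of RLE-type factors. The deposited scaling thus takes most regions as unchanged, and a general gain of acetylation by a deacetylase inhibitor would be removed by it. Replicate libraries differed by more than counting noise, with a chi-square per degree of freedom of 1.93 to 2.09 for each pair within a group, so no library was a copy of another.

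The planned count model was replaced by its planned fallback because the table holds RPKM. The main test was limma (version 3.58.1, R 4.3.3) on log2(RPKM + 1), with an intensity trend and robust empirical Bayes, butyrate against vehicle without covariates, and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate those of weak regions. Regions with a mean RPKM under 1 over the 6 libraries were left out (722), a filter set after the range of values was seen and before any test. Fits of the recovered reads, chosen after seeing the data, were voom with the effective library sizes on all regions, voom on regions with at least 25 mean reads, and limma on log2(CPM + 0.5). Each fit was tested on simulated data drawn from the real means and spread, with 200 regions changed 1.5-fold or 2-fold in each of 5 simulations. Limma on log2(RPKM + 1) gave 4.77% of the unchanged regions a p under 0.05.

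A total of 25 gene lists was fixed before the data were examined, with 489 distinct genes. Of these, 235 were measured: their region with most reads within 5 kb of the TSS had a mean RPKM of at least 1. Each gene was represented by its region with the most reads within 5 kb of the TSS, and lists with at least 3 measured members were tested with limma's camera (preset correlation 0.01), with camera with an estimated correlation and fry as alternatives. Regions named in the text follow a rule set at the same time, which took the 6 with the smallest p in each direction where none passed. From each list it took the member with the smallest p, or the 3 smallest for the tuft cell, butyrate transport and histone deacetylase lists. Regions called in the authors' deposited table or by the read-based fits are named as well, after their values were seen. Annotation classes were compared with Fisher's exact test. The mouse reference used for GC content and start sites was GRCm38 with GENCODE release M21, and all 11251 regions lay within its chromosomes; 8066 of them overlapped the TSS of a protein-coding gene.

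Alternatives covered the scaling (RLE-type, reads in regions, upper quartile), the filter, the pseudocount, the threshold, a cyclic loess correction, the choice of region per gene and leaving out each library. The share of reads in regions and the ratio to input were planned and could not be computed from the columns used.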

Results

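The data set measured acetylation of histone H3 at lysine 9 (H3K9ac), a mark of active promoters and enhancers, by chromatin immunoprecipitation and sequencing in epithelial cells from the terminal ileum of wild-type C57Bl/6 mice. Mice had received butyrate, a short-chain fatty acid made by gut bacteria and an inhibitor of histone deacetylases, at 150 mM for 7 days, or vehicle. There were 3 H3K9ac libraries per group, and the 2 input libraries, 1 per treatment, were not analysed here. The deposited table held 11251 regions, of 500 to 14052 bp with a median of 1417 bp. It gave RPKM, the reads per kilobase of region scaled to the depth of the library, for the 6 H3K9ac libraries. Of these regions, 10196 (90.6%) lay within 5 kb of an annotated transcription start site (TSS). The values corresponded to 1255251 to 1828591 reads in regions per library, and the median region had 82 to 120 reads per library. The labels do not say that each library came from a separate mouse, so the p-values measure the spread between libraries, part of which may be technical. The fits also drew each region's spread toward that of the other regions. Its SE and p-value thus do not rest on its own 6 values alone. All libraries had been scaled to nearly the same sum over regions (a spread of 1.28%). A change of acetylation shared by all regions could therefore not be seen, and every difference given here is relative to the other regions.

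The study compared histone acetylation in the epithelial cells of butyrate and vehicle mice. Few loci were called as different, and in calls with at least 100 mean reads the differences were below 2-fold. H3K9ac was lower with butyrate at an upstream region, at -25096 bp from the TSS of Gata4, a zinc-finger transcription factor of the gut epithelium. It was also lower at Irf2bp2, which encodes a corepressor that partners with IRF2, and both calls held whichever library was left out. Calls that were lost without some libraries were lower at Nfil3, a basic leucine zipper repressor tied to the circadian clock, and at a region over the TSS of Prdm16, and higher at Fos, a subunit of the AP-1 transcription factor, at Pmp22, a membrane protein of myelin and epithelia whose groups overlapped, and at an upstream region, at -7047 bp from the TSS of Arl4d, an ARF-like small GTPase. These calls came from models of the reads recovered from the RPKM values, while limma on log2(RPKM + 1), the main test, called 0 of 10529 regions at an adjusted p of 0.05.

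By limma on log2(RPKM + 1) the smallest Benjamini-Hochberg adjusted p was 0.49. An unadjusted p under 0.05 was found at 765 regions (7.27%), 353 higher and 412 lower with butyrate, where 526 were expected by chance. The median log2 fold change over all tested regions was 0.00 with an SD of 0.17. The median half-width of its 95% interval was 0.26, and 33 regions differed by over 1.5-fold on this scale. In 1364 regions (13.0%) all libraries of one group lay above all of the other, where chance gives 10%. On the recovered reads, limma's voom called 16 regions, 8 higher and 8 lower, and 8 of the 16 had under 25 mean reads. With only regions of at least 25 mean reads it called 9 of 9048, and limma on log2(CPM + 0.5) called 7. In data simulated for this comparison, limma on log2(RPKM + 1) found 29.1% of the regions changed 1.5-fold and 76.0% of those changed 2-fold, with 2.1% false calls. Voom on regions of at least 25 reads found 63.2% and 92.4% of the changed regions it tested, with 4.7% false calls. These shares leave out changed regions with fewer reads, which the limma shares include. Voom on all regions found 54% and 84.2%. Of regions with at least 100 reads changed 1.5-fold, limma on log2(RPKM + 1) found 42.6% and voom on at least 25 reads 84.4%.

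The regions called in all 3 of these read-based fits numbered 7, of which 3 were higher and 4 lower; their log2 fold changes, SE and voom adjusted p below are those of voom on regions of at least 25 reads. Irf2bp2 (chromosome 8, 126587933 to 126595524, mm10, covering the TSS) had 7.44 ± 0.27 RPKM in vehicle and 5.75 ± 0.31 in butyrate (SD, n = 3 each). Its log2 fold change was -0.37 ± 0.07 (SE), with a voom adjusted p of 0.00029. The intergenic region upstream of Gata4 (chromosome 14, 63268829 to 63271904), which overlaps a further Gata4 start site in GENCODE, had 3.51 ± 0.32 and 2.12 ± 0.48 RPKM (log2 fold change -0.71 ± 0.13, voom adjusted p 0.00029). The Gata4 promoter region itself (chromosome 14, 63242312 to 63249303) had 3.57 ± 0.13 and 3.21 ± 0.16 RPKM, with all butyrate libraries below all vehicle libraries. By voom on all regions its log2 fold change was -0.15 ± 0.08 (unadjusted voom p 0.074). By limma on log2(RPKM + 1) it was -0.12 with an unadjusted p of 0.26. Fos (chromosome 12, 85471531 to 85479300, the whole gene with its TSS) had 6.97 ± 0.28 and 8.70 ± 0.66 RPKM on a mean of 1290 reads. Its log2 fold change was 0.31 ± 0.06 with a voom adjusted p of 0.0015. Arl4d (chromosome 11, 101657713 to 101659275, intergenic) had 2.84 ± 0.064 and 4.63 ± 0.64 RPKM, a 1.63-fold ratio (voom adjusted p 0.014). The region at the Arl4d TSS differed less, with 2.62 ± 0.46 and 3.22 ± 0.56 RPKM. Nfil3 (chromosome 13, 52977997 to 52981998, first intron and TSS) had 3.35 ± 0.45 and 2.37 ± 0.10 RPKM (voom adjusted p 0.017). Pmp22 (chromosome 11, 63131251 to 63135427, intron and TSS) had 3.80 ± 0.48 and 5.22 ± 1.1 RPKM (voom adjusted p 0.015), with overlapping groups. The last of the 7, a region over the non-coding gene 5930403L14Rik and the TSS of Prdm16, a PR-domain transcription factor (chromosome 4, 154635029 to 154636825), had 5.49 ± 0.31 and 3.78 ± 0.91 RPKM (voom adjusted p 0.038). Neither Pmp22 (FDR 0.172) nor the Prdm16 region (FDR 0.116) was called in the authors' deposited table.

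Irf2bp2 and Gata4 passed voom on regions of at least 25 reads whichever library was left out, with adjusted p of 0.00072 to 0.017 and 0.00019 to 0.045. Fos missed it without library S2 (0.088) and without S6 (0.094). Nfil3 passed it only without S3 (0.0026), its other values being 0.3 without S1, 0.1 without S2, 0.063 without S4, 0.083 without S5 and 0.19 without S6. Arl4d missed it without S1 (0.12), S3 (0.11), S4 (0.097) and S6 (0.17). The Prdm16 region missed it without S1 (0.21), S3 (0.14), S5 (0.43) and S6 (0.2), and Pmp22 without S2 (0.31), S3 (0.14), S5 (0.4) and S6 (0.24).

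**Figure D1:**
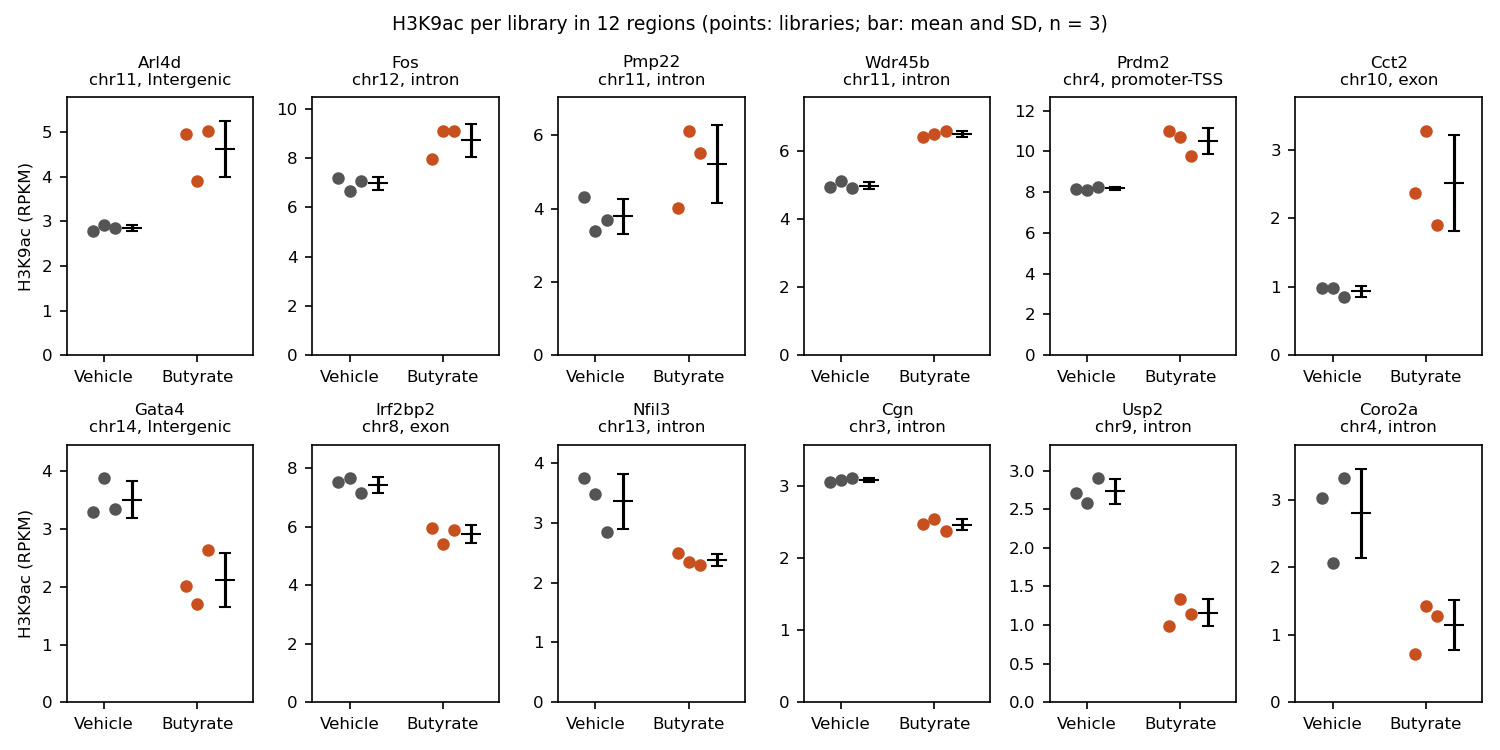
H3K9ac (RPKM, y axes from 0) in 12 regions, 6 higher (top) and 6 lower (bottom) with butyrate; points are the 3 libraries of each group, and bars give the mean and SD. At Gata4 the vehicle libraries lie between 3.30 and 3.88 RPKM and the butyrate libraries between 1.71 and 2.64, whereas the groups of Pmp22 overlap.

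In the authors' deposited table, whose threshold was an FDR of 0.1, 28 regions were called, 11 higher and 17 lower with butyrate, and 14 of them had an FDR under 0.05. In all 28 the libraries of one group lay entirely above those of the other. The 21 that passed the filter of the main test all had the same direction in limma and an unadjusted p under 0.05. Calls with at least 100 mean reads numbered 15, with absolute log2 fold changes of 0.32 to 0.71. Among these, the authors' deposited table gave Wdr45b, an autophagy protein, a log2 fold change of 0.39 (FDR 0.00538), Arf5, a small GTPase of the Golgi, 0.38 (FDR 0.0539), and Prdm2, a PR-domain histone methyltransferase, 0.36 (FDR 0.0682). On the lower side the authors' deposited table gave -0.33 for Cgn, which encodes the tight junction protein cingulin (FDR 0.0332), -0.38 for Cfl1, the actin-severing protein cofilin (FDR 0.0682), and -0.34 for the splicing factor Hnrnpl (FDR 0.0682). Further lower calls of the authors' deposited table were -0.36 for Ptgfrn (FDR 0.0731), -0.48 for Vstm5 (FDR 0.0507), and -0.53 for a promoter shared by A230020J21Rik and the heme exporter gene Flvcr1 (FDR 0.0332).

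Between 25 and 100 mean reads lay Coro2a, Srms and Parp8, a member of the PARP family, to which the authors' deposited table gave 0.65 (FDR 0.0682). Another 10 of the 28 calls had under 25 mean reads, and their absolute log2 fold changes in the authors' deposited table were 1.24 to 3.09. The furthest was a 500 bp region in the first intron of Utrn, which encodes the dystrophin homologue utrophin (chromosome 10, 12861157 to 12861657). There the 3 vehicle libraries held 15, 12 and 11 reads and the butyrate libraries 0, 3 and 1. Sbsn, Bcat1, Slc20a1, Mir1941 and Usp2 were the others lower, and Cct2, Mir5119 (over the TSS of Cdk12), Cntnap2 and Mir181a-2 those higher. The voom calls under 25 reads that the authors' deposited table did not call were Dennd5b, B4galt4 and Cyp4f17, higher, and Scap and 1810026B05Rik, lower, all with 9 mean reads or fewer. Each of these names is that of the nearest annotated start. The regions of Utrn, Usp2, Cct2, Slc20a1, Cntnap2, B4galt4, Scap and Cyp4f17 also overlapped the gene so named. Those of Mir1941 and Mir181a-2 overlapped the genes Krt80 and Nr6a1 instead. The regions of Sbsn, Bcat1, Dennd5b and 1810026B05Rik overlapped no protein-coding gene, and that of Bcat1 lay 102693 bp from its start. Of the 207 regions in the table under 9 mean reads, 15 had a log2 ratio within 0.5 of 0, against 115 to 126 for the other 9 ways to split the 6 libraries.

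**Figure D2:**
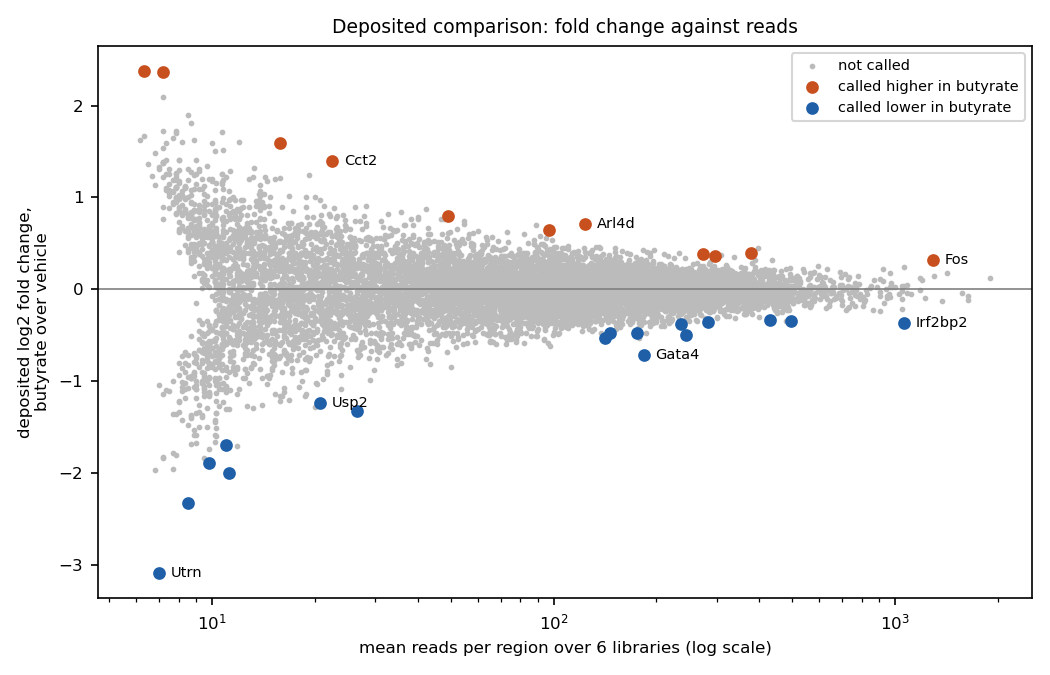
The authors' deposited log2 fold change (butyrate over vehicle, y axis) of all 11251 regions against mean reads per region over the 6 libraries (x axis, log scale); coloured points are the 28 regions called in the deposited table. Calls with at least 100 reads have absolute log2 fold changes of 0.32 to 0.71, those under 25 reads 1.24 to 3.09, and below 9 reads few regions lie near 0.

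No region passed limma on log2(RPKM + 1), so the regions with the smallest p in each direction were named in its place, none of them passing. Higher with butyrate were, besides Arl4d and Prdm2, Cct2, a subunit of the TRiC chaperonin (0.934 ± 0.079 against 2.51 ± 0.70 RPKM, on 22.5 reads), and Srms, a Src-like kinase (2.09 ± 0.26 against 3.62 ± 0.42). The others higher were Crlf2, the receptor chain for thymic stromal lymphopoietin (2.10 ± 0.46 against 3.68 ± 0.44), and Slc41a3, a magnesium transporter (2.11 ± 0.16 against 3.48 ± 0.41). Crlf2 and Slc41a3 lay at promoters, Cct2 over exon 2 and Srms over exon 1. Lower were an intronic region of Usp2, a ubiquitin-specific protease (2.73 ± 0.16 against 1.16 ± 0.17), Pfkfb3, a regulator of glycolysis (4.78 ± 0.37 against 3.23 ± 0.082), and Coro2a, an actin-binding coronin (2.80 ± 0.66 against 1.14 ± 0.37). The others lower were Gdpd5, a glycerophosphodiesterase (5.24 ± 0.50 against 3.56 ± 0.32), Gse1 (4.22 ± 0.75 against 2.57 ± 0.19) and Ttc22 (5.02 ± 0.20 against 3.61 ± 0.13). At Usp2 and Coro2a the regions closer to the TSS were nearer to equal, with 7.79 ± 0.59 and 7.03 ± 0.83 RPKM at 1 start site of Usp2, 2.74 ± 0.50 and 2.85 ± 0.39 at another, and 5.23 ± 0.27 and 4.62 ± 0.16 at Coro2a.

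Gene lists fixed before the data were examined were compared at 1 region per gene, within 5 kb of its TSS, on the log2(RPKM + 1) scale. Of the measured genes of fatty acid oxidation and ketogenesis 13 of 18 were lower with butyrate, with a median log2 fold change of -0.11 (camera p 0.0042, adjusted p = 0.088; adjusted p = 0.76 with an estimated correlation). Its member with the smallest p was Ehhadh, the peroxisomal bifunctional enzyme (-0.37 ± 0.13, SE). Further members were Acadvl, the very-long-chain acyl-CoA dehydrogenase (-0.33 ± 0.14), Pdk4, a pyruvate dehydrogenase kinase (-0.39 ± 0.20), Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane (-0.14 ± 0.11), and Etfdh, which was higher (0.17 ± 0.12). The list did not pass Benjamini-Hochberg adjustment over the 21 lists tested with camera, and it did with fry (adjusted p 0.033), which asks only whether members move one way. Of all 25 lists 0 passed with camera, 3 had an unadjusted p under 0.05, and 4 had fewer than 3 measured members and were not tested. Adjusted over the list alone, 1 member of any list passed, the goblet cell list's Kcnk6, and over all regions tested 0 passed. By voom, 7 members of lists with at least 3 measured genes passed over the list alone, Elf3, Klf5, Cgn, Nfil3, Abcc2, Abcg5 and Kcnk6, all lower with butyrate. List members beyond those set by the naming rule were chosen after their values were seen.

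Transcription factors of the intestinal epithelium were lower at 10 of 15 measured members, with a median of -0.10 (camera p 0.023, adjusted p = 0.16; adjusted p = 0.83 with an estimated correlation). On recovered reads the list passed (camera on voom, adjusted p 0.041), and so it did with fry's mixed test (adjusted p 0.038). Elf3, an ETS factor of epithelial differentiation, had -0.20 ± 0.08 (6.42 ± 0.44 against 5.45 ± 0.11 RPKM). The Krüppel-like factor gene Klf5 had -0.16 ± 0.10, the homeobox gene Cdx1 -0.15 ± 0.08 and Hnf4a 0.02 ± 0.09. The list's camera p ran from 0.0047 to 0.12 when a library was left out. Tight and adherens junction genes were lower at 12 of 17 members, with a median of -0.09 (camera p 0.069, adjusted p = 0.36, and adjusted p = 0.83 with an estimated correlation). Their smallest p was at Cgn (3.09 ± 0.024 against 2.46 ± 0.082 RPKM), and Tjp1, which encodes the scaffold protein ZO-1, had -0.16 ± 0.09, whereas Epcam had 0.13 ± 0.07. This list passed fry's mixed test (adjusted p 0.038) and not fry's directional test (0.46). Of the circadian clock genes 7 of 12 were lower (median -0.03, camera p 0.10), led by Nfil3 (-0.36 ± 0.11), with Cry1 at -0.19 ± 0.09 and Arntl at -0.20 ± 0.11.

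Genes for butyrate transport and sensing went both ways, 4 of 7 measured members being lower (median -0.03, mean 0.04, camera p 0.78). The sodium-coupled monocarboxylate transporter genes were higher without passing, Slc5a8 by 0.34 ± 0.16 (1.58 ± 0.48 against 2.24 ± 0.26 RPKM) and Slc5a12 by 0.20 ± 0.19, and Bsg, the chaperone of the proton-coupled transporters, had -0.11 ± 0.10. Histone deacetylase and acetyltransferase genes were higher at 8 and lower at 7 of 15 members (median 0.02, camera p 0.78). Ncor1, a corepressor that binds deacetylases, had -0.17 ± 0.08, the acetyltransferase gene Ep300 0.15 ± 0.07, and the deacetylase gene Sirt6 -0.14 ± 0.10, none passing.

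Tuft cell genes, of a chemosensory cell type that starts type 2 immunity, were mostly outside the regions of the table, with 5 of 28 measured. Ltc4s, for leukotriene synthesis, had -0.27 ± 0.14, Cd24a 0.28 ± 0.20 and Plcg2 0.04 ± 0.10, and the list's median was 0.01 (camera p 0.92). Of the epithelial response to type 2 cytokines 7 of 14 genes were measured, 3 lower and 4 higher (median 0.04, camera p 0.78), and Stat6, which signals for these cytokines, had -0.17 ± 0.09. Goblet cell genes were measured at 4 of 18, 2 higher and 2 lower (median 0.05, mean -0.03, camera p 0.64), and the potassium channel gene Kcnk6, -0.40 ± 0.13 (3.00 ± 0.55 against 2.02 ± 0.15 RPKM), passed when adjusted over the list alone (limma adjusted p 0.033). Paneth cell and antimicrobial genes were measured only at Pigr, the polymeric immunoglobulin receptor (-0.17 ± 0.14), and enteroendocrine genes at 0 of 22. Stem cell and Wnt target genes were lower at 5 of 9 (median -0.16, camera p 0.26), led by Znrf3, a Wnt receptor ubiquitin ligase, at -0.25 ± 0.10.

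Enterocyte absorption genes were lower at 12 of 22 and higher at 10 (median -0.02, camera p 0.75), with Apoc3, an apolipoprotein, at -0.22 ± 0.12. The ileal bile acid genes were even at 4 and 4 (median 0.00, camera p 0.58), and the exporter gene Abcc2 had -0.21 ± 0.10. Cholesterol synthesis genes were lower at 7 of 11 (median -0.04, camera p 0.70; Idi1, -0.23 ± 0.12), and xenobiotic metabolism genes at 7 of 10 (median -0.06, camera p 0.26), with the aryl hydrocarbon receptor gene Ahr at -0.21 ± 0.13. Cell division genes split 7 and 7 (median 0.01, mean -0.01, camera p 0.98); the thymidylate synthase gene Tyms had 0.32 ± 0.11. Cyclin-dependent kinase inhibitors and p53 targets were lower at 4 and higher at 5 (median 0.01, camera p 0.66). Among them Cdkn1a, the cell cycle inhibitor p21, had 5.60 ± 0.32 RPKM in vehicle and 6.04 ± 0.25 in butyrate, with a log2 fold change of 0.09 whose 95% interval ran from -0.08 to 0.26. Interferon response and antigen presentation genes were higher at 11 of 17 (median 0.06, camera p 0.15), among them the immunoproteasome gene Psmb8 (0.35 ± 0.10; 3.22 ± 0.11 against 4.39 ± 0.45 RPKM). Inflammatory signalling genes were higher at 7 of 10 (median 0.04, camera p 0.17), with Nos2, the inducible nitric oxide synthase, at 0.57 ± 0.19. Ribosomal protein genes, kept as a reference, had a median of 0.00 over 16 members (camera p 0.77), with Rps23 at -0.18 ± 0.11.

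Markers of other cell types that an epithelial isolate could hold were mostly not among the regions. T cell and intraepithelial lymphocyte genes were measured at 5 of 24, and all 5 were lower with butyrate (median -0.14, camera p 0.023, adjusted p = 0.16; adjusted p = 0.83 with an estimated correlation). The camera p of this list ran from 0.013 to 0.2 when a library was left out. Tcf7, which the stem cell list also holds, had -0.29 ± 0.15 and Cd2 -0.40 ± 0.21. Myeloid genes were measured at 3 of 17 (median -0.10, camera p 0.40; Cd14, -0.14 ± 0.13), stromal genes only at Vim (-0.22 ± 0.24), and B and plasma cell genes at 0 of 16.

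**Figure D3:**
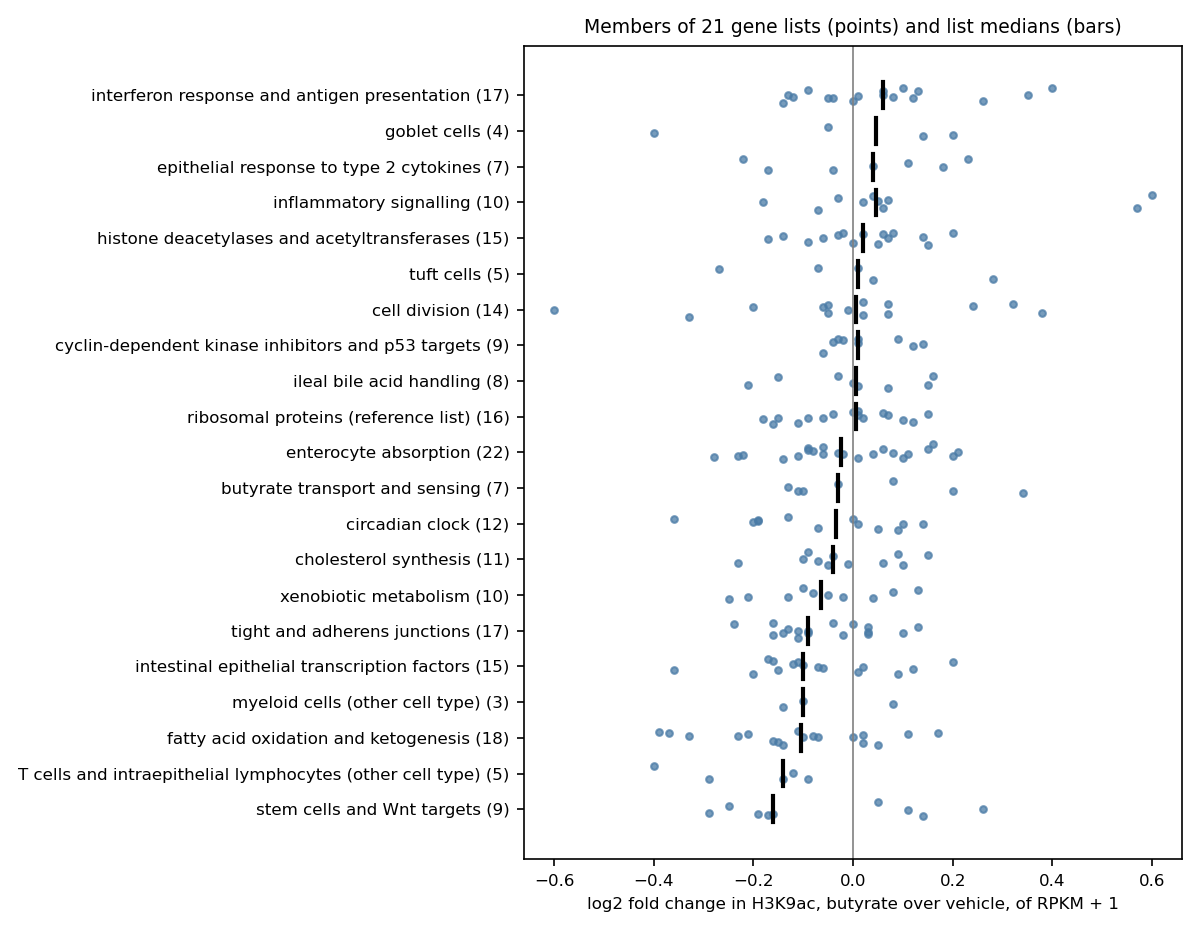
Log2 fold change in H3K9ac (butyrate over vehicle, of RPKM + 1, x axis) of each measured member (points) of the 21 gene lists with at least 3 measured members, with list medians (bars) and the number measured in parentheses; vertical scatter within a list has no meaning. Medians run from -0.16 for stem cells and Wnt targets to 0.06 for interferon response and antigen presentation.

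Where in genes the differing regions lay was compared through the table's own annotation. As 0 regions passed limma's adjusted test, those with an unadjusted p under 0.05 were used. Promoter-TSS regions made up 116 of the 353 higher regions (32.9%) and 107 of the 412 lower ones (26%), an odds ratio of 1.39 (95% interval 1.01 to 1.93; Fisher's exact test, two-sided, p 0.038). Against the regions with a larger p, of which 28.1% were promoter-TSS, neither set differed (p 0.054 for higher, 0.37 for lower). Neighbouring regions are not independent replicates, and the odds ratio was 1.06 (p 0.75) when regions were instead divided by overlap with a protein-coding TSS in GENCODE. Median log2 fold changes were 0.005 over promoter-TSS regions, -0.001 over introns and -0.008 over intergenic regions.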

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

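The fits of recovered reads and the GENCODE start sites were chosen after seeing the data. By limma, 0 regions passed under the other scalings, filters, pseudocounts, thresholds, cyclic loess and without each library (0 to 0), with 680 to 828 regions at an unadjusted p under 0.05 when a library was left out against 765 with all. The fits of recovered reads moved the count: voom called 16 regions, voom on regions of at least 25 reads 9, and limma on log2(CPM + 0.5) 7. The main test had less power in deep regions of the simulated data. Of 1.5-fold changes on at least 100 reads it found 42.6%. Voom on at least 25 reads found 84.4% of these and limma on log2(CPM + 0.5) 83.7%. Whether lower power accounts for every region called by the read-based fits alone was not tested. The count of 9 became 2 without S6, 4 without S3, 5 without S1, 6 without S4, 7 without S2 and 9 without S5. For gene lists, 0 passed with camera under RLE-type scaling, scaling by reads in regions, each region choice and each library left out (0 to 0). Upper-quartile scaling and cyclic loess were not run on the lists. With an estimated correlation camera passed 0. By contrast, fry passed 1 (directional) and 2 (mixed) and camera on voom 1, and fry asks another question than camera. Without each library the camera p ran from 0.0066 to 0.011 for fatty acid oxidation, 0.0047 to 0.12 for epithelial transcription factors and 0.013 to 0.2 for T cells. The odds ratio of promoter-TSS regions, 1.39 with the main fit, missed 0.05 in 12 of the alternatives. Among the 12 were no filter (1.26), at least 50 reads (1.34), voom (1.25), voom on at least 25 reads (1.38) and log2(CPM + 0.5) (1.22). The sign of every region (1.07) and GENCODE start sites (1.06) missed it as well. The rest lay among the other scalings, pseudocounts, cyclic loess and fits without a library. When a library was left out the odds ratio ran from 1.23 to 1.48, and the cause was not tested. All calls of the authors' deposited table that were tested kept their direction (100% to 100% without each library). Their groups lay entirely apart, so leaving out a library could not have reversed them. The region of Vim, at -0.22 with all libraries, ran from -0.45 to 0.0025 when a library was left out, reversing without Vehicle library S3 (0.0025). No paired analysis was possible because the columns carry no replicate numbers of the labels. For the same reason the replicate block was not run. The planned count-model alternatives were not run because the design set limma for a table of RPKM, although reads could be recovered. The input-based filter and ratio were not run because no input columns were used. The share of reads in regions was not run because the columns gave effective library sizes and no read totals. Depth limits regions under 25 mean reads, where a few reads set the fold.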

Other observations

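Tests chosen only after the result was seen were those of how regions came to be listed, of the share of epithelial cells, of the immediate early genes, and the splits of the libraries for regions with p under 0.05 and for voom calls.

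Fos and its partner Jun were both higher with butyrate, by 0.28 ± 0.07 and 0.22 ± 0.07 (limma log2 fold change and SE), with Dusp1 at 0.16 ± 0.08, while Ier3 had -0.31 ± 0.19 and Egr1 -0.13 ± 0.09. Of 16 measured immediate early genes, which respond within minutes to growth factors, stress and cell handling, 7 were above 0. The hypothesis that the list rose as a whole was not borne out: its median was -0.006, where random lists of the same size reached 0.082 at their upper 2.5%. Whether a part of the list rose together was not tested, and only Fos passed in the read-based fits.

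No protein-coding TSS lay in 12 (42.9%) of the 28 regions called in the authors' deposited table, against 28.3% of all regions. This went mostly with few reads: 9 of the 12 had under 25 mean reads, where 85.6% of all regions held none, and of the 15 calls with at least 100 reads only that of Arl4d held none. At Coro2a and Arl4d the region at the TSS had ratios of 0.88 and 1.23 against 0.41 and 1.63 at the called region. Usp2 had 0.90 and 1.04 at regions over 2 of its start sites against 0.43 at the called one. Whether called and TSS regions of a gene differ from each other was not tested. A second region near Srms (chromosome 2, 181214067 to 181214781) had a ratio of 0.58, opposite to the called region of that gene at 1.74, on 15.2 mean reads.

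More regions than chance gives had p under 0.05 by limma, 765 in the real split of the libraries and 532 in the highest of the others, and the 10 splits are too few for a share under 0.05; as many or more came in 1 split, the real one. After removing each library's trend with GC content there were 764 (highest other 544), and after thinning all libraries to the smallest 746 (highest other 573), so neither GC content nor unequal depth accounts for the excess. The share stayed at 6.46% or more whichever library was left out. The share exceeded that of the other splits both under 100 mean reads, at 9.54% (others 6.16% to 7.2%), and at 100 reads or more, at 5.21% (others 2.39% to 3.27%). By voom the share was 8.83% in regions of at least 200 reads (highest other 5.87%). In the 288 regions with p under 0.05 and at least 100 reads the lower group had a mean of at least 1.68 RPKM, more than the higher group had in 18.1% of all regions of the table. By that measure the lower group alone could have been listed, but region means are not known to be what the listing used. Whether listing for a peak in 1 group gave the excess thus cannot be told, under 100 reads or above, since how regions were called is not given. In the weakest regions of the table the values had the form that such a listing would give. Under 9 mean reads, 15 of 207 regions had a log2 ratio within 0.5 of 0, against 115 to 126 in the other splits. For regions chosen this way the shares given by chance would not hold. Butyrate treatment stays open as the biological explanation, as do differences between cages or days of isolation, which the labels do not give; for voom calls the real split gave 16 and the highest other 3, again with 1 of 10 splits as large. Of these 16 calls 8 had under 25 mean reads, and voom on regions of at least 25 reads gave 9 in the real split and 4 in the highest other (1 of 10 splits as large).

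H3K9ac at fatty acid oxidation genes was lower with butyrate by an unadjusted camera p of 0.0042, and the list did not pass adjustment (adjusted p = 0.088; 0.76 with an estimated correlation). The smallest p of the other splits was 0.14, where 10 splits are too few for a share under 0.05 (1 split gave a p as small, the real one). Region width, GC content and reads did not by themselves give such a median: -0.11 lay at the 0.19 percentile of 10000 random lists matched on these. Members of the random lists were drawn singly, so any correlation between members of the real list was left out. With that correlation estimated, the unadjusted camera p was 0.036. The list was also followed up because its p was the smallest of the 21 tested, so the percentile overstates the evidence. A smaller share of epithelial cells in the butyrate isolates cannot be told apart: the median lay 0.08 below that of enterocyte absorption genes (-0.08), and the bootstrap interval of this difference, -0.21 to 0.04, held 0. The measured markers of T cells (median -0.14) and myeloid cells (-0.10) were lower as well, where a smaller epithelial share would raise them, though on 5 and 3 genes, and the p of the T cell list ran from 0.013 to 0.2 when a library was left out. Lower acetylation of these genes with butyrate may be a response to the treatment, and this stays a hypothesis. Over all lists, 3 had p under 0.05 in the real split and 2 in the highest other, with 1 of the 10 splits as large.

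The largest fold changes of the authors' deposited table were in regions with few reads, 7 of the 28 calls having under 15 mean reads. Large ratios there were more frequent in the real split: 64 regions under 25 reads had the groups apart with a ratio of at least 2.5, against 19 in the highest other split. This cannot exclude counting noise, since noise selected by a listing on 1 group would show only in the real split. A candidate explanation is that such regions entered the table because a peak was called in the reads of 1 group: the smallest mean of the higher group over all regions was 0.421 CPM in the real split and at most 0.331 CPM in the others, as a floor on a group's mean would give. In regions under 15 reads the groups lay apart in 22.6%, against 7.65% to 9.56% for the other splits and 13.1% in the remaining regions, where chance gives 10%. If regions were chosen this way their fold changes and p-values would overstate the difference, and calls such as Utrn, Sbsn, Bcat1 and Cntnap2 would need input-corrected coverage or new libraries to be judged.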
